A study of Mus musculus with 8 samples.

How the data were processed

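The samples were cells from adult mouse lung stroma, 4 control mice and 4 mice carrying SmoM2, an activated form of the Hedgehog transducer Smoothened. In both groups a tamoxifen-inducible Cre recombinase expressed from Gli2 switches on a yellow fluorescent reporter, and in the SmoM2 group it also switches on SmoM2. Per the labels' protocols, tamoxifen was given into the peritoneum at 200 mg per kg per day for 5 days to activate the pathway in the SmoM2 lungs, and the dosing of the controls was not given in the sources used here. Lungs were digested with enzymes, live single cells positive for the reporter were sorted by flow cytometry, and polyadenylated RNA was sequenced, per the labels' protocols. The titles number 8 different animals, so p-values measure the spread between mice.

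The authors deposited 2 tables. The first holds estimated (expected) counts per Ensembl gene for 8 libraries, and the submitters' processing notes name FastQC, HISAT, StringTie and DESeq with the mm10 build, without versions or roles. The deposited expected counts were already whole numbers and were used without further rounding. They summed to 91.6 to 111.6 M units per library. The most frequent value above 0 was 5 units in all 8 libraries, held by 672 to 771 genes, against 490 to 584 genes at 4 units and 257 to 318 genes at 6 units. One sequenced fragment was therefore taken to add 5 units, an assumption that the values do not settle against 4. It gives about 18.3 to 22.3 M fragments per library, and 3 fragments, the most that a count of 0 allows, are then 15 units. Counting error is set by the fragments, not by the units. The table has 49671 gene identifiers, of which 30158 had a value above 0 in some library.

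The second table is the authors' own comparison. Per the file headers it gives the authors' normalised mean signal per group, their ratio (fold change), its log2 value, and p-values before and after adjustment. Dividing the deposited counts by median-of-ratios size factors gave the authors' group means to within a relative difference of 2.3e-09, so the deposited comparison was read as SmoM2 over control. Values from that table are named as the authors' wherever they are given.

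The column names show each library's group and a number from 1 to 4, but not which animal it came from, so libraries are named by group and column number. Gene symbols came from the reference table for 99.3% of identifiers, and from the authors' table for 145 others. Coordinates are 1-based, from the GENCODE release M21 annotation of the same build (mm10, also called GRCm38). Sex was read from Xist and Y-linked genes: each group held 2 male and 2 female libraries. No pair of libraries differed by as little as sampling noise, since the chi-square statistic over its degrees of freedom, with values divided by 5, lay between 22.8 and 105.0 for all pairs, so all 8 were kept as separate replicates.

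The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, glmQLFit with robust dispersion) on the deposited counts, with TMM factors, genes kept by filterByExpr and Benjamini-Hochberg adjusted p under 0.05, with the group as the sole term. It tested 20162 genes. Standard errors are the absolute log2 fold change over the square root of the F statistic, and intervals are 95% intervals from the same fit. CPM values use the TMM library sizes. DESeq2 1.42.0 and limma 3.58.1 were used for alternatives and for list tests. The test, the groups, 26 gene lists, most alternatives and the rule for naming genes were fixed before the data were examined.

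Lists were tested with camera on the edgeR counts at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 26 lists. A list's level in a library is the mean log2 CPM of its members with a prior count of 2. Group differences of levels were tested with an exact two-sided permutation test over the assignments of 8 libraries, whose smallest possible p is 0.0286. A gene counted as measured if it passed the expression filter, and for each list the members were also counted as called with p adjusted over the list alone.

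The naming rule took (a) any called member of the Hedgehog lists, and Gli1, Ptch1, Hhip, Smo and Gli2 in any case, (b) the 10 largest changes in each direction among called genes with a mean of at least 5 CPM, no overlap between the groups and no predicted gene model, and (c) for each other list up to 4 called members in each direction or, with none called, the 2 members with the highest mean CPM. With no gene called by edgeR, part (b) named none, and it was applied to the DESeq2 calls instead, a use chosen after the edgeR count was seen. Not every gene that the rule names is given in the text. Other genes are named as chosen after their values were seen.

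On data simulated for the 20162 genes of this comparison from the real means and library sizes, edgeR recovered 1 of 50 genes changed 1.5-fold, 18 of 50 changed 2-fold, 40 of 50 changed 3-fold and 38 of 50 changed 4-fold, with 2 false calls. DESeq2 recovered 13, 34, 47 and 44 of them with 72 false calls. In a further simulation of the same kind, a list of 15 genes shifted by 0.5 on the log2 scale was found by camera, and none of the 25 other lists was called. Genes were drawn independently of each other there, so it does not show how camera behaves on lists with correlated members. The estimated correlation of the real mesothelial list, for example, was 0.68.

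Alternatives were RLE and upper quartile factors, DESeq2, limma-voom with sample quality weights, no expression filter, a filter at 5 CPM in 4 libraries, a non-robust fit, sex as a covariate without Xist and Y-linked genes, leaving out each library, adjusted p under 0.01, and a test against a 1.5-fold change. Those added after seeing the data are named with the results that depend on processing.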

Results

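RNA was sequenced from reporter-positive GLI2+ stromal cells sorted from the lungs of 8 adult mice, 4 control and 4 with the SmoM2 allele. The libraries held 91.6 to 111.6 M units of estimated count, about 18.3 to 22.3 M fragments at 5 units each, with group means of 100.32 M (control) and 101.58 M (SmoM2). Values above 0 were given for 23581 to 24801 genes per library. The most abundant gene in every library was Gsn, which encodes the actin-severing protein gelsolin and took 2.59% to 3.89% of the units. Mitochondrial genes took 1.37% to 1.61%. The single comparison of the design, SmoM2 against control, asks what active Hedgehog signalling does to gene expression in GLI2+ lung stroma.

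Genes that report Hedgehog activity had like mean levels in both groups. Gli1, the transcription factor that the pathway itself induces, averaged 99.3 ± 32.9 CPM in control and 101 ± 21.5 CPM in SmoM2-labelled libraries (SD, n = 4 each), a log2 fold change of 0.03 with a 95% interval from −0.54 to 0.60. Ptch1, the Hedgehog receptor and also a target of the pathway, averaged 172.5 ± 57.4 and 158.9 ± 50.8 CPM, a log2 fold change of −0.12 (−0.74 to 0.51). Hhip, which encodes a secreted Hedgehog-binding protein, averaged 353.3 ± 100.6 and 414.3 ± 197.6 CPM, a log2 fold change of 0.23 (−0.55 to 1.01). All 3 had an adjusted p of 0.9999 in edgeR's quasi-likelihood test, which by itself sets no bound on a change. The intervals do: a log2 increase above 0.60 lay outside that of Gli1, while that of Hhip reached 1.01. The libraries are called SmoM2-labelled from here on, since these targets do not show the activation that the label names.

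Hhip ranged from 257.6 to 495.1 CPM among the controls and from 213.8 to 682.2 CPM among the SmoM2-labelled libraries, so the spread between mice within each group exceeded the difference between the group means. Smo, the gene of which SmoM2 is an activated form, averaged 124.2 ± 13.3 and 129.0 ± 8.80 CPM, a log2 fold change of 0.05 (−0.17 to 0.28), and the sources used here do not say whether transgene reads were counted under it. Gli2, the gene that drives the recombinase, averaged 43.95 ± 6.0 and 42.7 ± 3.54 CPM, a log2 fold change of −0.04 (−0.30 to 0.22). In mm10, Gli1 (ENSMUSG00000025407) lies on chromosome 10 from 127329882 to 127341974, Ptch1 (ENSMUSG00000021466) on chromosome 13 from 63508328 to 63573598, and Hhip (ENSMUSG00000064325) on chromosome 8 from 79965851 to 80058006. Smo (ENSMUSG00000001761) lies on chromosome 6 from 29735503 to 29761365 and Gli2 (ENSMUSG00000048402) on chromosome 1 from 118834132 to 119053619.

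**Figure D1:**
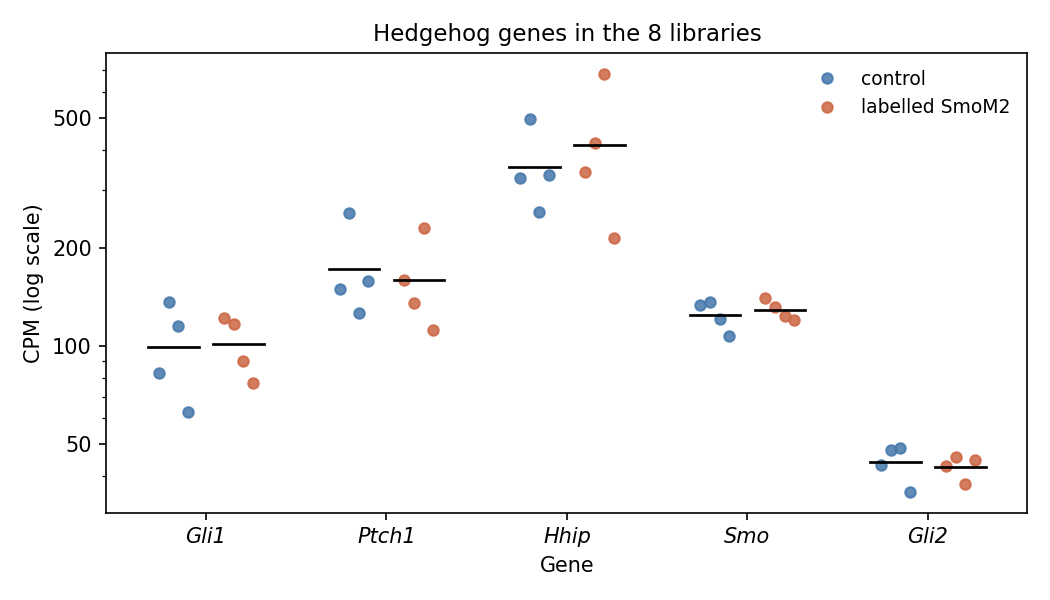
CPM (log axis) of 5 Hedgehog genes in each of the 8 libraries, with 1 point per library and a black line at the mean of each group of 4. For every gene the points of the control and SmoM2-labelled libraries overlap, as for Gli1 with means of 99.3 and 101 CPM.

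Of the 12 measured Hedgehog target genes, 5 were higher and 7 lower in SmoM2-labelled libraries, none of them called over all genes or adjusted over the list alone. The list's median log2 fold change was −0.07, with a camera adjusted p of 0.555 and an adjusted p of 0.785 with an estimated correlation. The forkhead factor Foxf1 averaged 163.2 ± 42.5 and 160.1 ± 20.3 CPM. Among the 17 Hedgehog pathway components, 5 were higher and 12 lower, none called, with a median of −0.05 and a camera adjusted p of 0.437 (0.785 with an estimated correlation). Without control 4 the components passed camera at the preset correlation, but not with an estimated one (median −0.09, adjusted p 0.0372). Boc, a Hedgehog co-receptor, averaged 405.2 CPM in each group.

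Over the whole transcriptome, edgeR's quasi-likelihood test called 0 of 20162 genes, so 0 were higher and 0 lower in SmoM2-labelled libraries. The smallest adjusted p was 0.138. At an unadjusted p under 0.05 edgeR counted 756 genes, 350 higher and 406 lower, against 1008 given by chance. The groups did not overlap for 492 genes, 2.44% of those tested, where chance gives 2.86%. DESeq2 called 67 genes, 31 higher and 36 lower, of which 27 had a mean under 1 CPM or were not tested by edgeR. In the simulation of the 20162 genes that edgeR tested, DESeq2 made 72 false calls, and 52 of its 67 calls here are among those genes. That simulation also held truly changed genes, which loosen the cutoff of the adjustment. The 72 is therefore not the count to be had when no gene changes, which was not simulated.

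The genes that DESeq2 called higher, taken by the naming rule, were led by Csnk1g1, a casein kinase 1 gene (ENSMUSG00000032384, chromosome 9 from 65908924 to 66045015), at 6.57 ± 1.66 CPM in control and 21.8 ± 4.32 CPM in SmoM2-labelled libraries. Its log2 fold change was 1.73 in edgeR, with an SE of 0.23, an edgeR adjusted p of 0.146 and a DESeq2 adjusted p of 2.753e-09. Tnfrsf10b, a death receptor for TRAIL, averaged 4.51 ± 2.05 and 12.6 ± 2.67 CPM, and Angptl7, a secreted angiopoietin-like protein, 24.1 ± 7.72 and 50.6 ± 7.81 CPM. Aspn, which encodes the matrix proteoglycan asporin, averaged 246.4 ± 25.1 and 467.5 ± 107.5 CPM. Entpd1, an ectonucleotidase gene, was at 55.7 ± 6.40 and 91.2 ± 16.5 CPM, and Nt5e, which encodes an enzyme that makes adenosine, at 7.72 ± 0.53 and 12.5 ± 2.32 CPM. The others were Arpp19, an inhibitor of protein phosphatase 2A (log2 fold change 0.77, SE 0.10), Pde10a (0.89, SE 0.18), Ptprj (0.71, SE 0.16) and Nupr1 (0.67, SE 0.10). Their edgeR adjusted p lay between 0.138 and 0.916.

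Of the genes that DESeq2 called lower and the naming rule takes, the largest difference was that of Colq, the collagen tail of acetylcholinesterase, at 44.4 ± 16.0 CPM in control and 15.5 ± 4.37 CPM in SmoM2-labelled libraries (edgeR log2 fold change −1.52, SE 0.31, DESeq2 adjusted p 0.00161). Msln, the mesothelial surface protein mesothelin, averaged 101.2 ± 31.9 and 38.3 ± 12.5 CPM, and Upk3b, another mesothelial marker, 91.3 ± 29.4 and 38.4 ± 12.9 CPM. Gpm6a, also on that list, averaged 42.1 ± 18.2 and 16.9 ± 5.34 CPM. Bcam, a laminin-binding adhesion molecule, averaged 88.3 ± 15.1 and 40.6 ± 7.57 CPM, and the keratin gene Krt7 11.7 ± 1.67 and 5.81 ± 1.16 CPM. Slco2a1, a prostaglandin transporter, averaged 40.7 ± 4.30 and 20.02 ± 3.23 CPM. The endothelial adhesion gene Esam (log2 fold change −1.34, SE 0.30), AU021092 (−1.27, SE 0.26) and the glycogen-binding Stbd1 (−1.25, SE 0.24) were the others that the rule names. None passed edgeR's test, with adjusted p between 0.148 and 0.9999.

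The authors' deposited table has 15 genes with an adjusted p under 0.05, 9 higher and 6 lower in SmoM2. Of these, 13 were also called by DESeq2. The share called by the main test was 0%, which had to be so, since edgeR called no gene at all. Of the 15, edgeR tested 14, and 13 had an unadjusted p under 0.05 in edgeR. The direction was the same for 98.5% of the genes in both tables. The smallest adjusted p in the authors' deposited table was 2.25e-14 for Tmem95, with a mean of 0 in control and 92.43 in SmoM2. The next were Csnk1g1, with means of 657.4 and 2193, and the immunoglobulin variable segment Ighv14-2, with 82.81 in control and 0 in SmoM2. Both tables rest on the same 8 libraries.

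Mesothelial markers, genes of the cells that line the lung surface, were all lower in SmoM2-labelled libraries. All 10 measured members were below their control mean, with a median log2 fold change of −1.19. Adjusted over the list alone, 6 members passed edgeR's test (Upk3b, Cldn15, Muc16, Lrrn4, Msln and Gpm6a), and none passed over all genes. Lrrn4 averaged 21.2 ± 8.65 and 7.93 ± 3.08 CPM, and Muc16, which encodes a large surface mucin, 26.8 ± 14.8 and 11.3 ± 3.75 CPM. Wt1, a transcription factor of mesothelium, had the smallest difference, at 5.20 ± 3.34 and 4.53 ± 3.24 CPM. The list's level was lower by 0.94 on the log2 scale among males and by 1.21 among females (2 libraries per group in each).

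The camera adjusted p of the mesothelial list was 4.51e-19 at the preset correlation, and the adjusted p was 0.282 with an estimated correlation. The list level averaged 4.53 ± 0.50 in control and 3.45 ± 0.58 in SmoM2-labelled libraries, with an exact permutation p of 0.0857 (two-sided, 0.842 after adjustment over 26 lists). With sex as a covariate the adjusted p with an estimated correlation was 0.029, and over the alternatives in which it was computed it lay between 0.029 and 0.763.

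**Figure D2:**
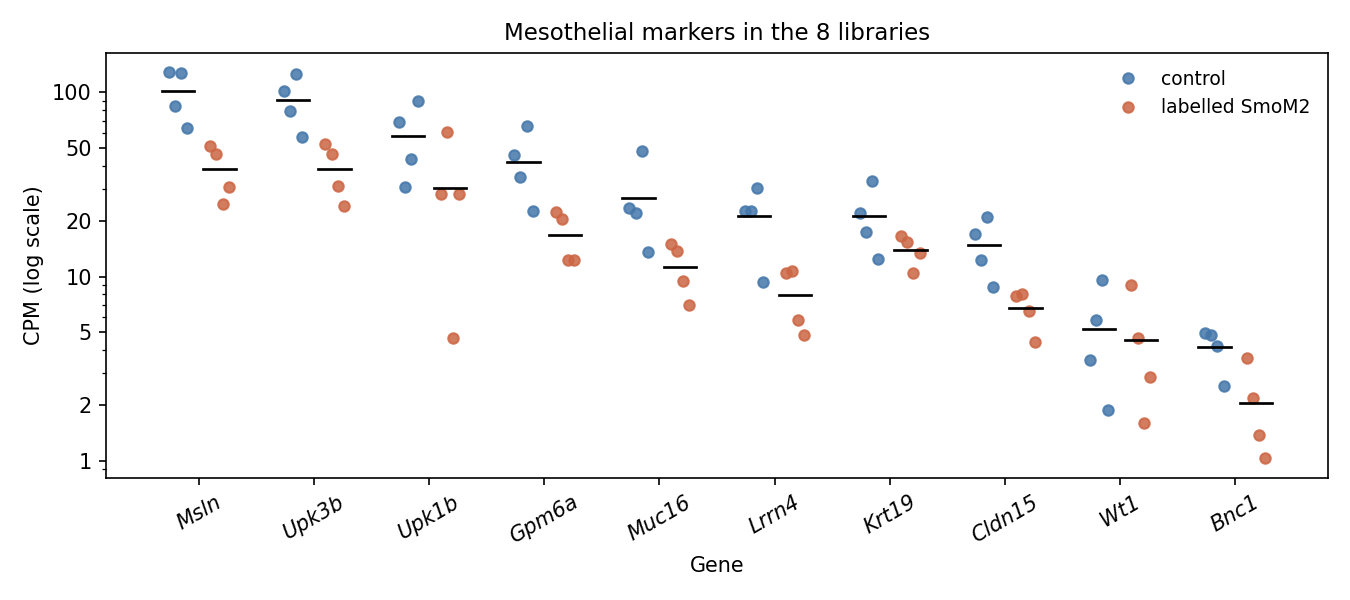
CPM (log axis) of the 10 mesothelial markers in each of the 8 libraries, with 1 point per library and a black line at the mean of each group of 4. All 10 means are lower in the SmoM2-labelled libraries, and Msln, Upk3b, Gpm6a and Cldn15 have no overlap between the groups.

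Markers of other cell types that a sort can let in were present at low to moderate levels. Endothelial markers were lower in SmoM2-labelled libraries, with 10 of 12 members lower, a median of −1.05 and a camera adjusted p of 6.21e-05 (adjusted p = 0.486 with an estimated correlation). Without control 4 the endothelial median was −0.19 and the camera adjusted p 0.0555. Esam alone passed adjusted over the list alone, while the 2 most abundant members went the other way: the angiopoietin receptor Tek averaged 37.2 ± 15.1 and 59.6 ± 29.9 CPM and Ramp2 40.9 ± 4.83 and 50.4 ± 13.5 CPM. Cartilage markers were higher in all 11 members, with a median of 0.58 and a camera adjusted p of 8.57e-04 (adjusted p = 0.768 with an estimated correlation). Col2a1, the main collagen of cartilage, averaged 211.6 ± 183.5 and 361.9 ± 218.5 CPM, and Chad 200.6 ± 170.1 and 357.7 ± 212.0 CPM, so the spread between mice exceeded the difference. Without control 4 or without SmoM2 1 the cartilage medians were 0.30 and 0.31 and the camera adjusted p 0.183 and 0.11, while without control 2 or control 3 they were 1.28 and 0.34 and the list still passed, again not with an estimated correlation. Immune cell markers were higher in 16 of 18 members, with a median of 0.49 and a camera adjusted p of 9.90e-04 (adjusted p = 0.768 with an estimated correlation). The lysozyme gene Lyz2 averaged 319.2 ± 78.6 and 438.7 ± 201.9 CPM, and Cd74 189.1 ± 54.8 and 235.4 ± 112.9 CPM. Without SmoM2 4 the immune median was 0.01 and the camera adjusted p 0.854, and without SmoM2 1 the median was 0.76. The immune call was also lost under limma-voom (median 0.31, adjusted p 0.0598).

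Epithelial markers did not pass (13 of 15 lower, median −0.30, camera adjusted p 0.226), with the surfactant gene Sftpc at 387.1 ± 403.5 and 247.9 ± 217.0 CPM and Abca3 at 84.5 ± 9.41 and 88.2 ± 14.3 CPM. The epithelial list passed at the preset correlation, but not with an estimated one, without control 1 or SmoM2 3 (medians −0.44 and −0.81, camera adjusted p 0.0304 and 0.00218), and its median was 0.33 without control 4. Pericyte markers (median −0.12, camera adjusted p 0.555) included Lamc3 at 275.2 ± 44.0 and 368.0 ± 138.2 CPM and Abcc9 at 279.9 ± 55.1 and 315.3 ± 65.4 CPM. Schwann cell markers had a median of −0.03 but a camera direction of higher (adjusted p 0.730), with Mbp at 11.5 ± 2.80 and 10.1 ± 2.76 CPM and S100b at 7.42 ± 5.04 and 9.49 ± 4.77 CPM. Cardiac muscle markers (median −0.28, camera adjusted p 0.475) were low, with Actc1 at 8.42 ± 4.2 and 8.01 ± 4.13 CPM and Tnni3 at 2.76 ± 0.70 and 2.21 ± 0.72 CPM, and passed without control 4 at the preset correlation, but not with an estimated one (median −0.36, camera adjusted p 0.0123). Without control 2 the cardiac median was −0.09 (camera adjusted p 0.924). Red blood cell markers (median 0.76, camera adjusted p 0.185) included the alpha-globin genes Hba-a1 at 6.92 ± 4.41 and 12.7 ± 12.2 CPM and Hba-a2 at 5.58 ± 3.30 and 9.45 ± 8.07 CPM. The red blood cell median was 0.02 without SmoM2 2, and the list passed at the preset correlation without control 1, SmoM2 3 or SmoM2 4 (medians 1.15, 1.06 and 1.07, camera adjusted p 0.0315, 0.0242 and 0.00295) but not with an estimated one. It also passed at the preset correlation in DESeq2 (median 0.77, adjusted p 0.034) and with sex as a covariate (0.47, adjusted p 0.028), but not with an estimated correlation under the sex covariate, a test not run for DESeq2. The 2 globin genes are near-identical copies, so their split is uncertain.

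The 5 stromal lists had medians between −0.30 and 0.31 on the log2 scale. Alveolar fibroblast markers were lower in 15 of 16 members, with a median of −0.20 and a camera adjusted p of 1.14e-05 (adjusted p = 0.587 with an estimated correlation). The alveolar median was −0.08 without control 4 (camera adjusted p 0.016) and −0.37 without SmoM2 3. Inmt averaged 3526 ± 799.8 and 3143 ± 718 CPM and the receptor gene Pdgfra 1748 ± 293 and 1966 ± 155 CPM. Wnt2, a distal lung Wnt ligand, was the member that passed adjusted over the list alone, at 25.2 ± 2.09 and 13.5 ± 1.63 CPM (log2 fold change −0.90, SE 0.12). It is named after its values were seen. Adventitial fibroblast markers were higher in 14 of 16 members, with a median of 0.31 and a camera adjusted p of 0.00603 (adjusted p = 0.768 with an estimated correlation). Gsn averaged 29730 ± 3300 and 32410 ± 6107 CPM and Dcn, which encodes decorin, 3459 ± 1060 and 4756 ± 1695 CPM. The adventitial call was lost without control 4, SmoM2 1 or SmoM2 4, with medians of 0.15, 0.13 and 0.17 and camera adjusted p of 0.668, 0.146 and 0.0874, and the median was 0.48 without SmoM2 3.

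Airway-associated fibroblast and myofibroblast markers were higher in 7 of 9 members (median 0.19, camera adjusted p 0.00603, adjusted p = 0.456 with an estimated correlation), and Aspn passed adjusted over the list alone. Enpp2, which makes lysophosphatidic acid, averaged 237.8 ± 42.9 and 311.7 ± 56.3 CPM. The airway-associated call was lost without control 3 or SmoM2 3 (medians 0.04 and 0.18, camera adjusted p 0.16 and 0.0564), and the median was 0.35 without control 2 and 0.29 without control 4. Smooth muscle contractile genes were lower in 10 of 12 members (median −0.30, camera adjusted p 0.025, adjusted p = 0.768 with an estimated correlation), with the kinase gene Mylk at 948 ± 130 and 749.3 ± 144.6 CPM and Smtn at 151.1 ± 36.3 and 143.7 ± 20.6 CPM. The smooth muscle call was lost without control 2, control 3, SmoM2 1 or SmoM2 4 (medians −0.11, −0.24, −0.23 and −0.17, camera adjusted p 0.462, 0.113, 0.255 and 0.34). Lipofibroblast and lipid handling genes did not pass (8 higher, 6 lower, median 0.04, camera adjusted p 0.609), with Lpl at 281.4 ± 53.9 and 297.4 ± 14.3 CPM and Scd1 at 230.3 ± 23.2 and 247.0 ± 63.9 CPM.

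Epithelial niche growth factors, the signals by which stroma supports epithelium, were lower in 16 of 19 members, with a median of −0.28 and a camera adjusted p of 1.14e-05 (adjusted p = 0.327 with an estimated correlation). Wnt2, shared with the alveolar list, again passed adjusted over the list alone. Bmp5 averaged 247.0 ± 18.1 and 200.3 ± 58.8 CPM, and the cytokine gene Lif 205.8 ± 141.9 and 240.3 ± 116.8 CPM. Wnt feedback genes did not pass (median 0.06 with a camera direction of lower, adjusted p 0.275), with Dkk3 at 622.2 ± 59.3 and 550.0 ± 97.0 CPM and Sfrp1 at 160.1 ± 38.2 and 233.2 ± 77.6 CPM. BMP and TGF-beta response genes did not pass (median −0.02 with a camera direction of higher, adjusted p 0.555), with Ccn2 at 1381 ± 271.5 and 1847 ± 452 CPM and Id3 at 897.1 ± 338.3 and 825.2 ± 133.9 CPM. Without control 2 the BMP and TGF-beta list passed at the preset correlation, but not with an estimated one (median 0.12, camera adjusted p 0.0377).

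Of the 15 collagen genes 8 were higher and 7 lower (median 0.07, camera adjusted p 0.111), with Col3a1 at 7017 ± 2363 and 6908 ± 1116 CPM and Col1a2 at 6287 ± 2064 and 6206 ± 1407 CPM. The collagen list passed at the preset correlation, but not with an estimated one, without control 1, control 2 or SmoM2 3 (medians 0.17, 0.11 and 0.12, camera adjusted p 0.00488, 0.0145 and 0.0088). Of 14 elastic fibre genes 11 were higher (median 0.09, camera adjusted p 0.111), with Ltbp4 at 5349 ± 507 and 6090 ± 702.7 CPM and Eln, which encodes elastin, at 3814 ± 1533 and 4002 ± 641.4 CPM. The elastic fibre list passed at the preset correlation, but not with an estimated one, without control 1 or SmoM2 3 (medians 0.16 and 0.14, camera adjusted p 0.0248 and 0.00779). Of 17 measured matrix proteases and inhibitors 10 were higher (median 0.05, camera adjusted p 0.555), with Timp3 at 3288 ± 611 and 3243 ± 466.5 CPM and Timp2 at 2365 ± 193 and 2558 ± 200.1 CPM.

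Cell cycle genes did not pass (14 of 18 higher, median 0.11, camera adjusted p 0.424), with Pcna at 55.6 ± 13.02 and 50.3 ± 13.1 CPM and Mcm4 at 41.2 ± 2.84 and 39.8 ± 4.05 CPM. The cell cycle list passed at the preset correlation, but not with an estimated one, without control 1 or SmoM2 2 (medians 0.47 and 0.26, camera adjusted p 0.00488 and 0.0203). Interferon response genes were higher in 12 of 14 members (median 0.29, camera adjusted p 0.0049, adjusted p = 0.768 with an estimated correlation), though the most abundant, Gbp2, averaged 85.2 ± 9.90 and 87.9 ± 18.2 CPM. The interferon call was lost without control 3 or SmoM2 3 (medians 0.26 and 0.00, camera adjusted p 0.128 and 0.578), and the median was 0.44 without SmoM2 1. Cytokine and chemokine genes had a median of −0.03 with a camera direction of higher (adjusted p 0.555), with the cyclooxygenase gene Ptgs2 at 703 ± 344.9 and 638.4 ± 312.2 CPM and Nfkbia at 483.5 ± 252.1 and 404.6 ± 101.8 CPM. Without control 3 the cytokine list passed at the preset correlation, but not with an estimated one (median 0.40, camera adjusted p 0.0388). Immediate early and heat shock genes, which tissue dissociation can induce, were lower in 16 of 17 members (median −0.17, camera adjusted p 0.0184, adjusted p = 0.785 with an estimated correlation). Fos averaged 5458 ± 732 and 4600 ± 1729 CPM and Egr1 4615 ± 691 and 4193 ± 1639 CPM. That call was lost without control 2, control 3, SmoM2 3 or SmoM2 4 (medians −0.20, −0.03, −0.21 and −0.03, camera adjusted p 0.0845, 0.683, 0.071 and 0.854), and the median was −0.28 without control 4, −0.32 without SmoM2 1 and −0.28 without SmoM2 2.

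Across the 26 lists, 11 passed camera at the preset correlation, 6 lower and 5 higher, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.282. Of the 11, 8 lost the preset call without at least 1 library, and the mesothelial, alveolar fibroblast and niche factor lists did not. Fry called 0 lists in one direction (smallest adjusted p 0.459) and 0 in either direction (0.0753). The exact permutation test of list levels gave a smallest adjusted p of 0.842. Its smallest possible p of 0.0286 before adjustment over 26 lists means that a single list could not pass it.

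**Figure D3:**
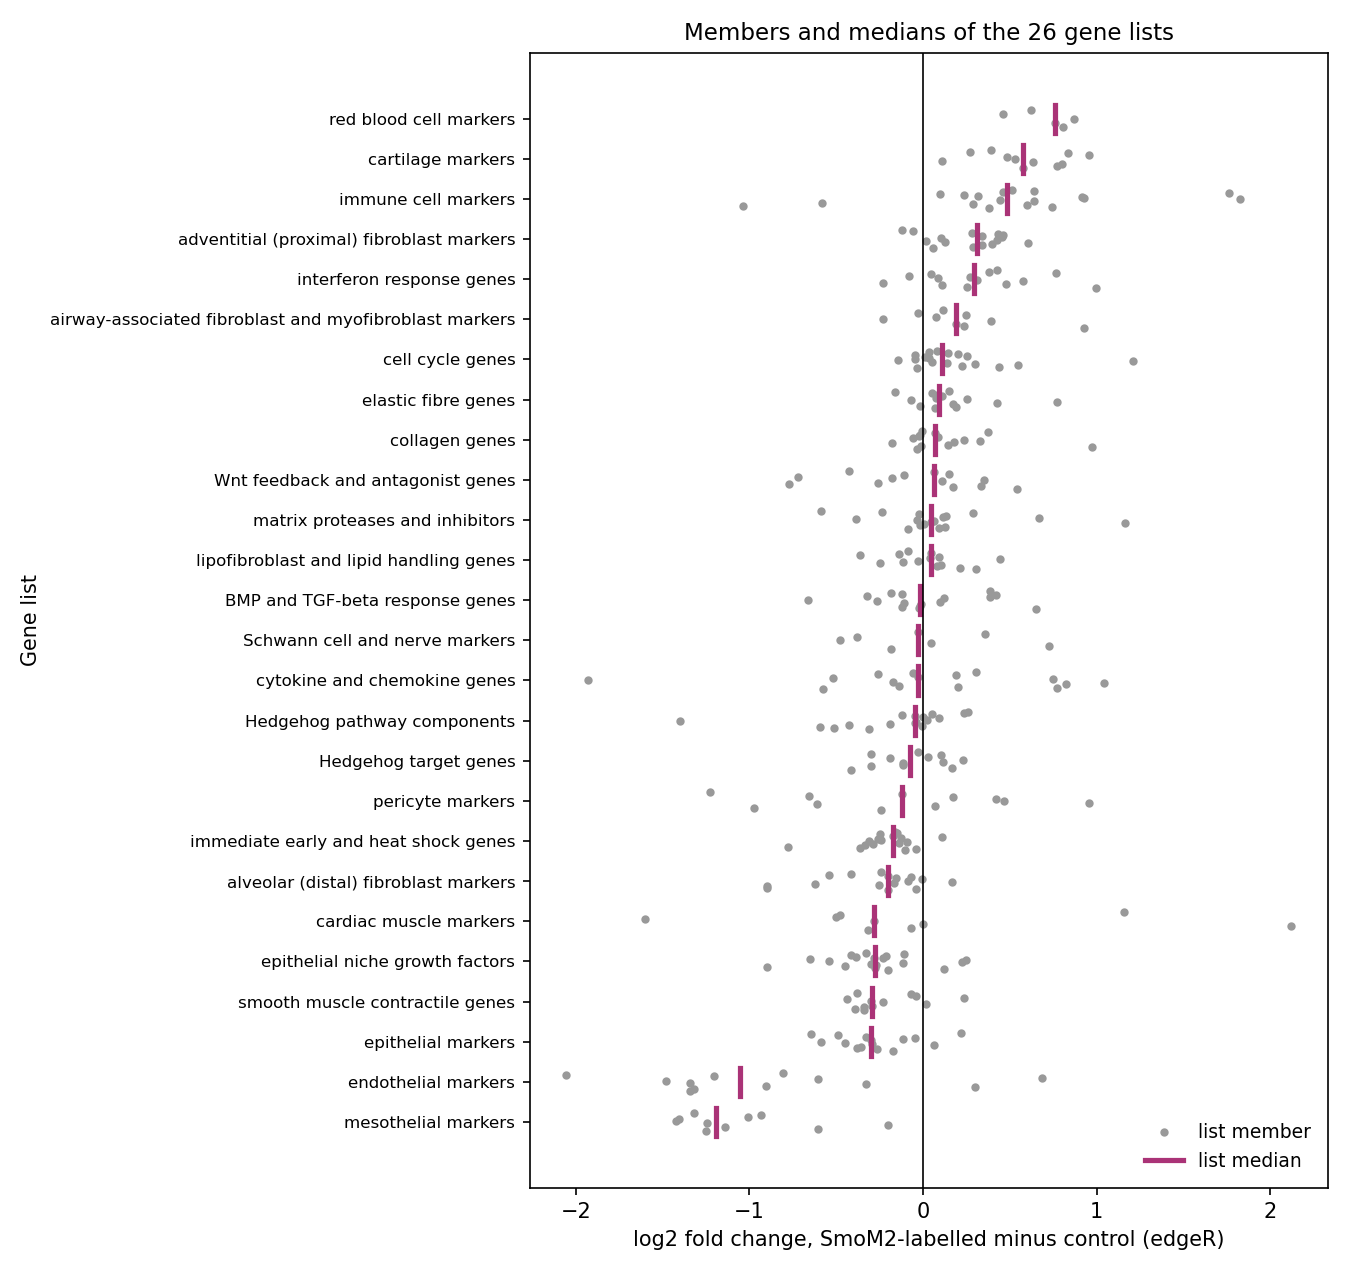
Log2 fold changes of the measured members (grey points) and the median (vertical bar) of each of the 26 gene lists, SmoM2-labelled minus control. The mesothelial list has the lowest median, −1.19, followed by the endothelial list at −1.05, and most other medians lie near 0.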

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

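The count of splits for edgeR, and the tests of the bound on a swap, of sex and of a lower mesothelial share, were chosen after the results they bear on were seen.

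Other divisions of the same libraries gave results as large as the real one, so chance is not excluded for the DESeq2 count or the count of lists. For edgeR the real split called 0 genes (756 at an unadjusted p under 0.05) and the highest other split 15, and since all 35 splits of the 8 libraries into 4 and 4 must reach 0, that comparison says nothing about chance. DESeq2 called 67 genes for the real split, 16 of the 35 splits called at least as many, and the highest other called 946. Camera at the preset correlation passed 11 lists for the real split, 15 of the 35 splits passed at least as many, and the highest other passed 17. The split with 15 edgeR calls and 946 DESeq2 calls sets control 1, control 4, SmoM2 1 and SmoM2 3 against the rest, which points to a structure of the libraries that crosses the groups.

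Hedgehog targets were at like levels in both groups, although the label names an activated Smoothened. If SmoM2 induces the targets, swapped libraries between the groups would leave another split with the targets apart. Over the 34 other splits the lowest adjusted p of Gli1, Ptch1 and Hhip in edgeR was 0.328, in the split of control 1, control 4, SmoM2 3 and SmoM2 4 (Gli1 at 62.7 to 89.7 CPM) from the rest (115.3 to 136.5 CPM). The largest 95% bound of a log2 fold change of the 3 genes over those splits was 1.3, under the 1.58 of a 3-fold difference, which argues against a swap that hides a 3-fold induction, while a swap with a smaller induction stays open (edgeR recovered 18 of 50 simulated genes changed 2-fold and 40 of 50 changed 3-fold). No biological explanation was tested, and a pathway that had returned to its control level, or few sorted cells with active SmoM2, stays open.

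Mesothelial markers were lower in SmoM2-labelled libraries, with a median log2 fold change of −1.19. Each group holds 2 males and 2 females, so a difference between the sexes that is alike in both groups cancels from the group difference. The list level also differed by −0.94 among males and −1.21 among females, with no overlap in either sex. The balance and these values argue against the sex of the mice as the cause. The largest move of the median toward 0 under RLE or upper quartile factors was 0.004, but these factors moved the median of all genes too little to decide. A library factor moves all genes of a library alike, so it cannot set these markers apart from the rest. The median log2 fold change of all 20162 tested genes was −0.004, but the scaling itself sets this value near 0, so it is no separate evidence. The gap between it and the list median of −1.19 does not depend on the factors, so scaling does not explain that gap. A candidate explanation is a lower share of mesothelial RNA: for 10 of the 10 markers the 95% interval of the fold change included the list median, but the intervals are wide and 3 of them also include 0, so this does not show 1 common fold, and the most abundant marker, Msln, was at 101.2 CPM in control and 38.3 CPM in SmoM2-labelled libraries. The sort was set to keep reporter-positive cells, but markers of other cell types were present nonetheless. Sftpc was at 162 to 207.2 CPM in controls 1 to 3 and at 991.8 CPM in control 4, and Lyz2 averaged 319.2 CPM in control. Mesothelial cells without the reporter, or their RNA, are therefore not excluded. None of the mesothelial markers is on another list. How many of them GLI2+ stroma also expresses, whether SmoM2 acts on these genes, and chance (exact permutation p 0.0857) stay open.

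Single libraries stood apart from the others of their group in 14 of 202 groups tested, where chance alone gives about 1 in 20. For the genes, values are log2 CPM: Ptprj was at 4.74 in control 1 against 4.32 to 4.36 in the other controls, and Stbd1 was at 5.06 there against 5.98 to 6.14. Nupr1 was at 6.70 in control 2 against 6.51 to 6.53. In control 4, Dcn was at 10.89 against 11.85 to 12.03, and Sftpc at 9.95 against 7.34 to 7.70. In SmoM2 3, Ltbp4 was at 12.30 against 12.63 to 12.67, and in SmoM2 4, Fos was at 11 against 12.34 to 12.53.

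For list levels, adventitial fibroblast markers were at 7.60 in control 4 against 8.44 to 8.57 in the other controls, and at 7.90 in SmoM2 3 against 8.64 to 8.78. Collagen genes were at 9.75 in SmoM2 3 against 10.20 to 10.29, and epithelial markers at 5.00 in control 4 against 3.41 to 3.64. The total of SmoM2 2 was 91.6 M units against 104.4 to 105.5 M in the others of its group. The 10 most abundant genes took 7.13% of control 4 against 8.86% to 8.92%, and mitochondrial genes took 1.61% of SmoM2 4 against 1.40% to 1.42%.

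In edgeR's test of the interaction of sex and group, with 2 libraries per sex and group, 1 gene passed, Fgf2 (386 genes at an unadjusted p under 0.05). Fgf2, a growth factor gene on chromosome 3 from 37348346 to 37410108, was at 11.3 and 8.8 CPM in male controls, 139 and 122 CPM in female controls, 126 and 166 CPM in male SmoM2-labelled libraries, and 11.3 and 9.26 CPM in female ones. The log2 interaction was 7.53, with an edgeR adjusted p of 0.00302. Nudt6 overlaps the end of Fgf2 on the opposite strand, so the reads of the 2 genes are uncertain there. Fgf2 was high in 4 libraries and low in 4. Each sex was high in 1 group and low in the other, which argues against sex alone as the cause. Whether the high and low values reflect how reads were assigned to gene models was not tested.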

How the results depend on the processing

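Alternatives chosen after seeing the data were the library split of control 1, control 4, SmoM2 1 and SmoM2 3 against the rest as a covariate together with sex, matched pairs of libraries (same sex and side of that split) as a block, values divided by 5, leaving out control 4 and SmoM2 3 together, and DESeq2 with sex. The number of digits in the animal number as a covariate, and the comparison of mice with 4-digit numbers alone, were not run because the columns are not tied to animals. The median of all genes stayed within 0.011 of 0 under RLE and upper quartile factors.

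Every alternative in edgeR or voom called 0 genes except 2. Where a test against no change called 0, 456 to 1287 genes had an unadjusted p under 0.05. The lowest count came from the filter at 5 CPM, which tested 11388 genes. The test against a 1.5-fold change, which asks for more, had 169. DESeq2 called 67 (31 higher, 36 lower), and with sex 92 (33 higher, 59 lower), of which 56 were shared. Matched pairs as a block called 2, both lower, Colq and Msln. Leaving out each library called 0 to 1 gene, lower in each case, the 1 being Gm20716 without SmoM2 4. The agreement with the authors deposited comparison, as the share of the authors' calls, was 86.7% for DESeq2 and 80% with sex. DESeq2 is another test, and for the rest the cause was not tested. Lists past camera at the preset correlation numbered 8 to 16 over the alternatives. Apart from leaving out single libraries, calls were lost for immune markers under limma-voom (median 0.31), smooth muscle and immediate early genes at an adjusted p under 0.01, smooth muscle genes with sex and the library split (−0.27), and airway-associated (0.08) and interferon genes (0.09) without control 4 and SmoM2 3. Calls were gained for red blood cell markers in DESeq2 (0.77, and 0.48 with sex) and with sex as a covariate (0.47), for elastic fibre (0.12), collagen (0.08) and epithelial (−0.21) lists with matched pairs, and for elastic fibre genes without control 4 and SmoM2 3 (0.16). None of the gained calls passed with an estimated correlation, which was not computed for DESeq2. In the comparison without covariates 0 passed with an estimated correlation and 0 with fry, which allow for correlated members.

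The signs of small differences turned as follows, and the cause was not tested. Under voom the log2 fold change was −0.02 for Gli1 and −0.04 for Gbp2, with medians of −0.21 for Wnt feedback and 0.05 for cytokine genes. With the filter at 5 CPM the medians were 0.19 for cytokine genes, 0.12 for pericyte and 0.09 for Schwann cell markers. With sex and the library split they were 0.13 for cytokine genes and 0.06 for Schwann cell markers. With matched pairs as a block they were −0.13 for Wnt feedback and 0.13 for cytokine genes, with Col3a1 at 0.03 and Col1a2 at 0.02. With values divided by 5 they were 0.08 for cytokine genes and 0.07 for pericyte markers. Without control 4 and SmoM2 3, matrix proteases were at 0.00, Hhip at −0.15, Gli1 at −0.08, Eln at −0.04, Gbp2 at −0.13 and Abcc9 at −0.06.

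Leaving out each library in turn changed the camera calls of lists as the report gives. The medians of the BMP and TGF-beta list without control 2 (0.12) and of the cytokine list without control 3 (0.40) changed sign, and both lists, whose camera direction with all libraries was already higher, passed at the preset correlation but not with an estimated one. It gave ranges of the median log2 fold change that reached or crossed 0 for the Hedgehog target genes list (−0.16 to 0.13), Hedgehog pathway components (−0.09 to 0.01), lipofibroblast genes (−0.05 to 0.12), Wnt feedback genes (−0.14 to 0.12), BMP and TGF-beta response genes (−0.17 to 0.13) and collagen genes (−0.03 to 0.17). So did matrix proteases (−0.13 to 0.11), cell cycle genes (−0.32 to 0.47), cytokine genes (−0.24 to 0.40), interferon response genes (0.00 to 0.44), epithelial markers (−0.81 to 0.33), pericyte markers (−0.24 to 0.04) and Schwann cell markers (−0.19 to 0.27). Among genes the ranges were −0.35 to 0.13 for Ptch1, −0.13 to 0.01 for Gli2, −0.12 to 0.45 for Hhip, −0.14 to 0.22 for Gli1 and −0.01 to 0.10 for Smo. They were −0.23 to 0.02 for Smtn, −0.09 to 0.21 for Scd1, −0.11 to 0.53 for Lif, −0.31 to 0.11 for Id3, −0.05 to 0.38 for Eln, −0.20 to 0.17 for Col3a1, −0.20 to 0.13 for Col1a2 and −0.13 to 0.07 for Timp3. They were −0.34 to 0.01 for Pcna, −0.10 to 0.02 for Mcm4, −0.39 to 0.17 for Ptgs2, −0.45 to 0.11 for Nfkbia, −0.11 to 0.12 for Gbp2 and −0.32 to 0.08 for Egr1. They were −1.44 to 0.42 for Sftpc, −0.06 to 0.13 for Abca3, −0.06 to 0.53 for Cd74, −0.03 to 0.81 for S100b and −0.47 to 0.21 for Actc1. Ranges that reached 0.00 were those of Fos (−0.40 to 0.00), Inmt (−0.33 to 0.00) and Gsn (0.00 to 0.23).

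The mesothelial median stayed between −1.42 and −1.01 when each library was left out, and kept its direction and its camera call at the preset correlation under every alternative that gave a list test. Of the 26 lists, 1 passed with an estimated correlation under sex as a covariate, the mesothelial list (adjusted p 0.029), whose adjusted p ran from 0.029 to 0.763 over the alternatives in which it was computed.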

Other observations

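Both tests in this part were chosen after the positions of the genes were seen.

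The libraries differed more across 1 division that crosses the groups than between the groups. The 4 libraries control 1, control 4, SmoM2 1 and SmoM2 3 had lower levels of cytokine and chemokine genes, at 5.06, 4.93, 5.02 and 4.92 log2 CPM, than control 2, control 3, SmoM2 2 and SmoM2 4, at 5.88, 6.05, 6.07 and 5.82. EdgeR called 15 genes between these 2 sets of samples, with 2904 at an unadjusted p under 0.05. Hexokinase 2 (Hk2) averaged 32.1 CPM in the first set and 108 in the second, the circadian deubiquitinase gene Usp2 29 and 80.6, and the NF-kB family genes Rel 30.6 and 59.8 and Bcl3 37.8 and 85.9. The median log2 fold change of the cytokine list was −0.75 (adjusted p 0.0352 with an estimated correlation). Markers of other cell types also moved with this division at the preset correlation, with a median of −0.81 for immune cell markers (camera adjusted p 1.03e-06) and 0.97 for epithelial markers (8.80e-06), though neither passed with an estimated correlation (adjusted p 0.65 and 0.658). The sets are not the study's groups, and each holds 1 male and 1 female library of each group. They were found by comparing all splits, so the p-values describe the division and do not test it.

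Other cell types varied strongly from mouse to mouse inside both groups. The level of cartilage markers ran from 3.08 (control 4) to 6.43 (control 2) in controls and from 4.2 to 6.63 in SmoM2-labelled libraries. Epithelial markers were highest in control 4 (5.00) and SmoM2 3 (4.61), and lay between 3.10 and 3.65 in the other libraries. Adventitial fibroblast markers were lowest in the same 2 libraries, at 7.60 and 7.90. Immune cell markers ran from 3.36 (SmoM2 1) to 5.37 (SmoM2 4), and cell cycle genes from 1.54 (control 3) to 3.14 (SmoM2 4).

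A gene chosen after its values were seen, Tmem95, had 0 units in all 4 controls and 71 to 144 units in each SmoM2-labelled library. Its mean in SmoM2-labelled libraries was 24.6-fold the value of 3 fragments over the control group, 0.0374 CPM at 5 units each. This ratio leaves out the spread between mice and rests on the assumed 5 units. The edgeR adjusted p was 0.138.

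Of the 50 genes with the smallest edgeR p, 10 lie on chromosome 9, which holds 5.84% of the tested genes. They include Csnk1g1, Arpp19, Nt5e, Slco2a1, Esam and Sema3f, and run from 37528078 (Esam) to 119350299 (Acaa1a). A local cause was tested by the number in 1 window of 20 Mb: 4 of the 50 genes shared a window, and 43.7% of 10000 random sets of 50 genes held as many. Of the 35 splits of the libraries, 6, the real one included, put as many of their top 50 on 1 autosome, with 13 in the highest other split. Neither test sets chromosome 9 apart from chance. The window test took the fullest window on any chromosome, so it does not test the count of 10 on chromosome 9. That count was not compared with random sets of genes.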
